A study of Homo sapiens with 4 samples.

How the data were processed

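RNA from naive CD4+ T cells of human cord blood was hybridised to Affymetrix exon arrays by the submitters. Per the labels' protocols, cells were kept in IL-2 medium, total RNA came from unstimulated cells or from cells stimulated for 24 h through CD3 and CD28 and was isolated on columns, and biotin-labelled sense targets were made with the manufacturer's whole transcript assay. The titles of the arrays put 2 in the naive and 2 in the activated group, with replicate numbers 1 and 2 in each. Whether the replicates came from separate donors or cultures is not given in the sources used here, so the p-values measure only the spread between these arrays, which may be technical.

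The table of values deposited by the authors holds 1 natural log value per probeset and array. Software, background correction, genome build and normalization between arrays are not given in the sources used here. The base of the log was settled from the values: among the 1000 most frequent values, the exponentials of 439 shared 12 fractional parts (to 4 decimals) under base e, against 26 under base 2 and 25 under base 10, a pattern that subtracting a background from whole intensities leaves. Values at the lowest level, read here as a background-subtracted value of 1, numbered 4392 and 3660 on the naive and 3749 and 4823 on the activated arrays. The design fixed before the data were examined allowed for a table already on a log2 scale or for a linear one. The natural logs were divided by the natural log of 2 to give log2 values, with the lowest level at 0, and were otherwise used as deposited. Any array-wide difference in brightness therefore stays in the values, whose medians differ slightly between arrays.

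Genes were named from the platform annotation of GEO, which can be old. Of the 272678 probesets, 251328 had 1 symbol, 8705 had several and 12645 had none; the last 2 kinds entered only the test of probesets. Of 16084 symbols, 13843 were current in the RefSeq gene table, 2155 were replaced through its synonyms, 82 were ambiguous and 4 unmatched and kept as they were. XIST and Y-linked genes were left out (28 genes, 315 probesets). The remaining 16034 genes had a median of 13 probesets and at most 178. A gene's value on an array is the mean log2 value of its probesets. Near background the size of a change in such a mean depends on how low values are treated, and probesets that respond weakly dilute it.

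Activated and naive arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, all 4 arrays, group as the only term), with 2 residual and 4.21 prior degrees of freedom and Benjamini-Hochberg adjustment; an adjusted p under 0.05 is called changed. Errors printed with log2 changes are the moderated standard errors, and errors of levels are SDs of 2 arrays. The same test was run on 272363 single probesets. Exon usage was tested with diffSplice of limma (F-test per gene, with a test of each probeset against the rest of its gene) in 7590 genes that had 4 or more probesets, were at or above the median gene level of 6.80 and used 109915 probesets at or above the median probeset level. Gene lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the data; p-values of lists are adjusted over all 25 lists. With the estimated correlation 0 lists were called (2 at an unadjusted p under 0.05), against 17 with the preset one. This loss was not a matter of correlation alone. For cytokines and chemokines the estimated correlation was 0.008, below the preset one, yet the unadjusted camera p went from 4.475e-05 to 0.0526. For cholesterol synthesis it was -0.0052, and the unadjusted camera p went from 0.000924 to 0.0682. The 2 settings thus differ in more than the correlation.

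The 25 lists, with 670 entries of which 618 were measured, were fixed before the data were examined, 5 of them holding markers of other cells, while a list of dendritic cell markers used only among the other observations was written afterwards; the count adjusted over the list alone uses only the list's members. The text names the 6 genes that rose most and the 6 that fell most among called genes with both activated arrays beyond both naive arrays and a level at or above the median, up to 3 called members of each list with the largest absolute change, the 6 genes with the smallest exon usage p, the called genes of the list for exon usage, and PTPRC in any case. Placeholder, immunoglobulin, T cell receptor and HLA genes were passed over. Other genes are named where stated, after their values were seen.

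The tests were checked on simulated data with known changes and the spread of these arrays. Of 16034 genes in the gene test, 28 of 100 with a simulated log2 change of 1 and 94 of 100 with a change of 2 were recovered, and 11 of 15634 unchanged genes were called. In the exon usage test, run on 7558 genes, 5 of 99 genes with 1 probeset shifted by 1.5 were recovered. With a shift of 3, 51 of 96 were recovered, and 0 of 7363 genes without a shifted probeset were called. All probesets of a gene with a simulated gene-level change moved alike. Calls that arise where probesets respond to a gene's change with different strength were therefore not checked. Simulated probesets also varied independently about their gene, so errors shared by some of a gene's probesets were not checked either. Of 272363 probesets, 713 of 1988 with a change of 2 were recovered and 49 of 268382 unchanged ones called. In each of these tests a smaller share was changed in the simulation than was called in the data, where 4995 of 16034 genes were called. The adjusted threshold was therefore stricter in the simulation, and the recovered shares cannot be read as those of the data. With the preset correlation camera called the raised list, and 4 of 100 unchanged lists had an unadjusted p under 0.05. With the estimated correlation the raised list was not called (camera unadjusted p = 0.00286). Simulated genes varied independently of each other, whereas the correlation estimated for the measured genes of mitosis and G2/M was 0.448. The 4 of 100 therefore cannot show how often the preset correlation falsely calls lists of correlated genes.

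Alternatives were quantile normalization, median centring of each array, the median of a gene's probesets as its value, filters on level, eBayes without a trend or robust, an unmoderated model, a minimum fold of 1.5 (treat), the replicate number as a block, other filters and a Simes test for exon usage, and leaving out each array in turn. Chosen after seeing the data were a raised floor, where every value below 6.09 (the median over arrays of the lower quartile) was set to it, an offset of 16 added to the values before log2, which had been planned only for a linear table, median centring for the named genes, and a block with crossed replicate numbers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.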

Results

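Gene expression was measured on Affymetrix human exon arrays in naive CD4+ T cells collected from human cord blood, the helper T cells that have not yet met antigen. The cells were kept in medium with interleukin 2 (IL-2) and were either left unstimulated or stimulated for 24 h with antibodies against CD3, part of the T cell receptor complex, and CD28, the main costimulatory receptor. The 4 arrays fall into 2 groups, with 2 naive and 2 activated arrays. An exon array carries several probesets per gene, most aimed at single exons, so that both the level of a gene and the relative use of its parts can be compared. Values for 272678 probesets were available on every array. The median probeset value on the log2 scale was 6.85 and 6.81 on the naive arrays and 6.88 and 7.04 on the activated arrays. Gene values of replicate arrays were closely related, with a Pearson correlation across genes of 0.981 between the naive and 0.980 between the activated arrays, against 0.854 to 0.872 between arrays of different groups. The number of arrays limits the precision of every value below.

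The first comparison asks which genes differed between activated and naive cells. Among changed genes at or above the median level, the transcription factor IRF8 rose most, from a log2 value of 5.24 ± 0.20 (SD, n = 2) in naive cells to 12.69 ± 0.36 (SD, n = 2) in activated cells, a log2 change of 7.45 ± 0.23 (SE). It was followed by TNFRSF9, the costimulatory receptor 4-1BB, with a change of 5.91 ± 0.16, by UHRF1, which maintains DNA methylation at replication (5.64 ± 0.17), and by the immunoregulatory surface protein CD200 (4.96 ± 0.17). DTL, a substrate receptor of a ubiquitin ligase active in S phase, rose by 4.83 ± 0.16, and MCM2, a subunit of the replicative helicase, by 4.58 ± 0.18. At that level the genes that fell most were P2RY8, a G protein-coupled receptor, with a log2 change of -4.33 ± 0.20, PIK3IP1, an inhibitor of phosphoinositide 3-kinase (-4.26 ± 0.16), and PNRC1, a nuclear receptor coactivator (-4.18 ± 0.21). SLFN5 of the Schlafen family (-4.07 ± 0.18), YPEL3 (-4.05 ± 0.22) and TCP11L2 (-4.03 ± 0.16) followed. The largest adjusted p of these 12 genes was 0.000228 (limma). Where a group lies near background the size of a change depends on how low values are treated: with low values raised to a common floor of 6.09, chosen after seeing the data, it was 6.48 for IRF8, 3.69 for UHRF1, -3.11 for P2RY8, -3.12 for PNRC1 and -2.44 for YPEL3. PIK3IP1 (-4.23) then led the falls, before SLFN5 (-3.97) and TCP11L2 (-3.96). Orders of size are given as deposited throughout, and several change with this floor.

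**Figure D1:**
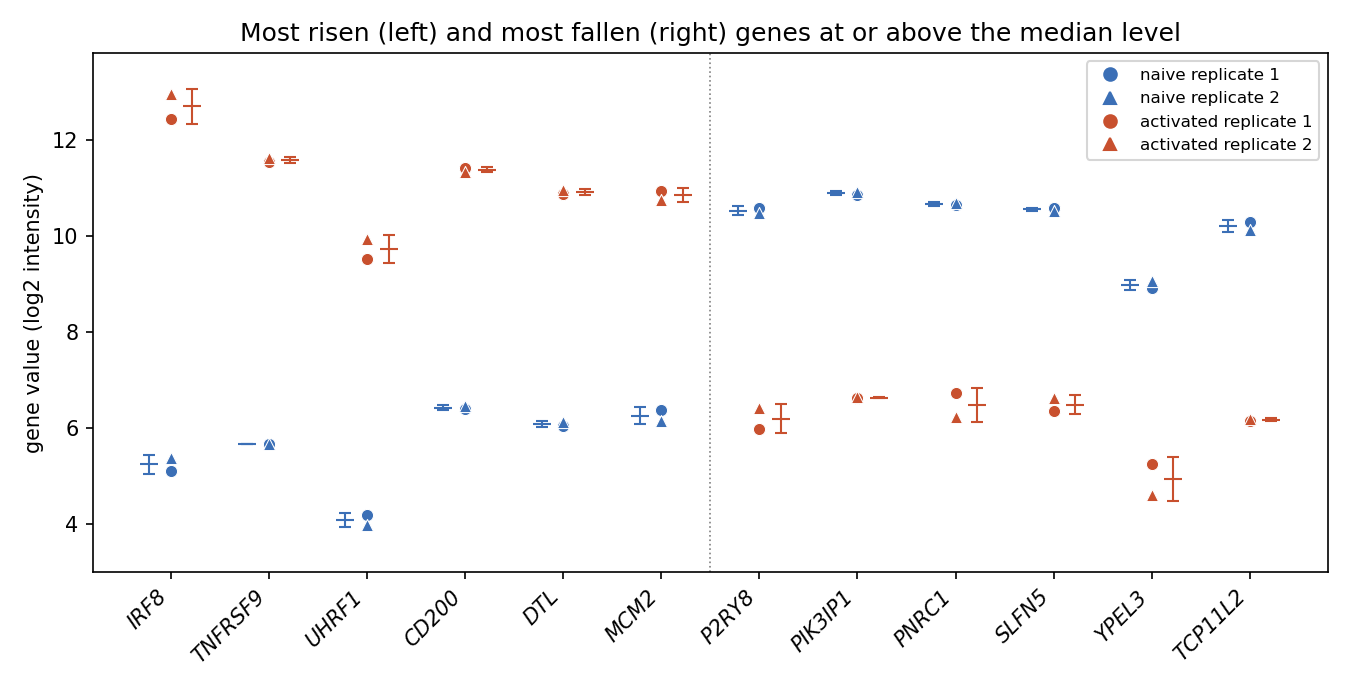
Gene values (log2 intensity, vertical axis) on each of the 4 arrays for the 6 genes that rose most and the 6 that fell most among genes at or above the median level; circles and triangles are single arrays, and the bars beside them show the group mean ± SD (n = 2). In every gene both activated arrays lie on the same side of both naive arrays, which the rule for naming these genes required. The values run from 12.43 and 12.95 against 5.10 and 5.38 in IRF8 to 6.14 and 6.19 against 10.28 and 10.12 in TCP11L2.

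Of 16034 genes tested, 4995 changed at an adjusted p under 0.05 (limma), 3522 higher and 1473 lower after activation, and by over 2-fold 1953 were higher and 623 lower. In all 4995 both activated arrays lay beyond both naive arrays, but with 2 arrays per group a gene whose groups overlap could not pass. This separation is therefore no further support for the calls. Over all genes it held for 62.7%, against 33.3% by chance. The balance of the directions depended on scaling. As deposited, 70.5% of the changed genes were higher, and the median log2 change was 0.07 over all genes and 0.32 over the genes at or above the median level. After quantile normalization 3064 genes were higher and 2563 lower (54.5% higher), and after median centring of each array 3479 were higher and 2422 lower (59.0% higher), with the median of all genes shifted by -0.13. Of the 4995 changed genes, 4520 (90.5%) also changed after quantile normalization, 0 of them in the opposite direction. Without naive replicate 1 the test called 2181 genes (1599 higher, 582 lower), and without naive replicate 2 it called 2117 (1504 higher, 613 lower). In both fits the lone naive array is assumed to vary like the activated pair. The counts rest on variance moderated across genes, since with 2 residual degrees of freedom the unmoderated model called 2 genes.

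Genes of T cell activation and of the naive state moved in opposite directions. Among 26 measured activation receptors, 21 rose and 1 fell, with a median log2 change of 1.46 (camera adjusted p = 1.33e-07; adjusted p = 0.234 with an estimated correlation). After TNFRSF9 and CD200, TNFRSF4, the costimulatory receptor OX40, rose most as deposited (4.77 ± 0.26 SE). With the raised floor its change was 2.75, below those of TFRC (3.39), IL2RA (3.31) and IL12RB2 (2.96), chosen after their values were seen. Of 33 cytokines and chemokines, 17 rose and 1 fell (median 0.58; adjusted p = 9.32e-05; adjusted p = 0.234 with an estimated correlation). They were led by the tumour necrosis factor family members TNF (4.57 ± 0.23), LTA (3.90 ± 0.17) and TNFSF14 (3.70 ± 0.13, or 2.89 with the raised floor). Of 34 genes listed as inducible transcription factors, 23 rose and 1 fell (median 1.06, camera adjusted p = 7.7e-09, or 0.234 with an estimated correlation). The list also holds TNFAIP3, which was among those that rose, and NFKBIA, neither of which is a transcription factor. NR4A2 (4.20 ± 0.16) and IRF4 (3.82 ± 0.21) came next after IRF8. Of 34 genes of the naive and quiescent state, 29 fell and the other 5 did not pass. Their median change was -2.03 (adjusted p = 4.26e-23; adjusted p = 0.234 with an estimated correlation). The transcription factor KLF2, which maintains quiescence and lymphoid homing receptors, fell by 5.69 ± 0.14 as deposited, from 9.57 ± 0.00 to 3.89 ± 0.20 (SD, n = 2). With the raised floor its change was -3.80, smaller than those of PIK3IP1 (-4.23) and SLFN5 (-3.97). Among 15 lineage transcription factors 5 rose and 4 fell, or 5 and 6 after quantile normalization. Their median was 0.18 and their mean 0.19, while camera gave the opposite sign (down, adjusted p = 0.715), and after quantile normalization the median was -0.10. TBX21, the Th1 factor T-bet, rose by 2.76 ± 0.16 and STAT4 by 1.48 ± 0.15, whereas RORA fell by 1.80 ± 0.12. Adjusted over the list alone, 22 activation receptors, 18 cytokines and chemokines, 26 genes of the inducible list and 6 lineage factors rose. In the same adjustment 5 lineage factors fell, and the counts of other calls in these lists were the same.

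The cell division programme rose throughout. All 41 measured genes of DNA replication and the G1/S transition were higher, with a median log2 change of 2.64 (camera adjusted p = 4.26e-23; adjusted p = 0.234 with an estimated correlation). Besides UHRF1 and MCM2, thymidylate synthase TYMS changed most, from 5.88 ± 0.20 to 10.30 ± 0.29 (SD, n = 2), a log2 change of 4.42 ± 0.21. All 38 genes of mitosis and G2/M were also higher (median 1.70; adjusted p = 3.37e-17; adjusted p = 0.309 with an estimated correlation). The largest changes were in cyclin A2 (CCNA2, 3.57 ± 0.18), the anaphase-promoting complex activator CDC20 (3.37 ± 0.17) and the condensin subunit NCAPG (2.92 ± 0.14). Adjusted over the list alone the same numbers passed, and all 41 and all 38 were also higher after quantile normalization.

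Among lists of biosynthetic and metabolic genes, some had members that fell or did not pass, and their medians were not tested against each other. Of 33 ribosome biogenesis genes all 33 were higher, with a median of 1.77 (adjusted p = 5.02e-16; adjusted p = 0.262 with an estimated correlation). They were led by MRTO4 (3.08 ± 0.17), BOP1 (2.61 ± 0.17) and RRP9 (2.60 ± 0.17). Of 17 genes of serine and one-carbon metabolism 15 were higher and 0 lower (median 1.86; adjusted p = 1.17e-08; adjusted p = 0.234 with an estimated correlation). The mitochondrial folate enzymes MTHFD2 (3.16 ± 0.18) and SHMT2 (2.51 ± 0.19) and the purine synthesis enzyme PAICS (2.28 ± 0.17) rose most. Among 18 aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 16 rose (median 1.20; adjusted p = 3.75e-07; adjusted p = 0.334 with an estimated correlation). WARS1 (3.36 ± 0.22), RARS1 (2.43 ± 0.17) and FARSB (2.26 ± 0.21) were in front. Of 27 genes of the unfolded protein and heat shock responses 20 rose and 1 fell (median 1.33; adjusted p = 2.69e-07; adjusted p = 0.309 with an estimated correlation). The chaperones HSPD1 (2.85 ± 0.19), HSPA9 (2.45 ± 0.17) and HSPA4 (2.32 ± 0.17) changed most. Of 23 glycolysis genes 15 rose and 3 fell (median 1.25; adjusted p = 0.00021; adjusted p = 0.485 with an estimated correlation). Rises included the lactate transporter SLC16A1 (2.88 ± 0.18) and the enzymes PGAM1 (2.69 ± 0.15) and PFKP (2.17 ± 0.20). The members that fell were PFKFB3, a regulator of glycolytic flux (-1.39 ± 0.20), PDK1, which inhibits pyruvate dehydrogenase (-0.76 ± 0.17), and the glucose transporter SLC2A3 (-0.57 ± 0.17), chosen after their values were seen. Of 21 cholesterol synthesis genes 10 rose (median 0.63; adjusted p = 0.00165; adjusted p = 0.244 with an estimated correlation). Among them were STARD4 (3.06 ± 0.16), which carries sterols, and the mevalonate pathway enzymes FDPS (1.59 ± 0.17) and PMVK (1.55 ± 0.16). Of 13 genes in the amino acid transport list 8 rose and 1 fell (median 0.64, camera adjusted p = 0.0302, or 0.573 with an estimated correlation). Membership rests on the fixed list, and what each member carries was not examined here. SLC1A5 (3.65 ± 0.17, or 3.06 with the raised floor), SLC43A3 (3.62 ± 0.19) and SLC7A5 (3.22 ± 0.17) rose above the rest. This last call was also lost without activated replicate 2 (adjusted p = 0.0738) and with the median of a gene's probesets as its value (adjusted p = 0.0643). Over all alternatives its adjusted p ranged from 0.0183 to 0.573. Adjusted over the list alone, 16 genes of serine and one-carbon metabolism and 14 of cholesterol synthesis were higher. Lower were 1 of cholesterol synthesis and 3 of the amino acid transport list, and the other counts did not change.

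Of 29 measured genes of T cell receptor signalling 14 fell and 3 rose, or 19 and 3 after quantile normalization, with a median log2 change of -0.60 (camera adjusted p = 3.83e-05; adjusted p = 0.522 with an estimated correlation). The largest falls were in the kinases TXK (-3.23 ± 0.17) and PRKCQ (-1.74 ± 0.23) and the adaptor FYB1 (-1.68 ± 0.18). Feedback inhibitors of signalling rose in 20 of 26 cases and fell in 3 (median 0.97; adjusted p = 4.24e-05; adjusted p = 0.262 with an estimated correlation). The phosphatases DUSP2 (3.73 ± 0.18) and DUSP4 (3.65 ± 0.20) and the Ras pathway inhibitor SPRY1 (3.12 ± 0.18) rose most. Among 32 interferon-stimulated genes 12 fell and 5 rose (median -0.27; adjusted p = 0.00278; adjusted p = 0.573 with an estimated correlation). MX2, an antiviral GTPase, fell by 1.77 ± 0.16, while the guanylate-binding proteins GBP5 (3.45 ± 0.15) and GBP1 (1.73 ± 0.17) rose. Over the genes at or above the median level the list's median was 0.01 and the call was lost (adjusted p = 0.145, within a range of 0.000354 to 0.573 over all alternatives). Of 24 apoptosis genes 7 rose and 3 fell, or 6 and 7 after quantile normalization, and the list was not called (median 0.20; adjusted p = 0.688). The survival genes BCL2L1 (2.82 ± 0.25) and BCL2A1 (2.56 ± 0.15) and the pro-apoptotic PMAIP1 (1.80 ± 0.22) rose. The change of PMAIP1 did not pass with the median of its probesets as the gene value (adjusted p = 0.0506, the highest of its alternatives; the lowest was 2.82e-09). Of 40 splicing regulators 22 rose and 4 fell, or 15 and 6 after quantile normalization with a median of 0.30 (median as deposited 0.58; adjusted p = 0.0229; adjusted p = 0.746 with an estimated correlation). HNRNPLL, a repressor of variable exons of CD45, rose by 1.95 ± 0.17, SRSF3 by 1.40 ± 0.18 and TRA2B by 1.39 ± 0.17. The call of the splicing list was lost after quantile normalization (adjusted p = 0.118), over the genes at or above the median level (0.378), without naive replicate 2 (0.116) and without activated replicate 2 (0.0633), and its lowest adjusted p over the alternatives was 0.00474. Adjusted over the list alone, 4 genes of T cell receptor signalling, 21 feedback inhibitors, 8 apoptosis genes and 24 splicing regulators rose, and 4 feedback inhibitors and 5 splicing regulators fell; the other counts were the same.

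**Figure D2:**
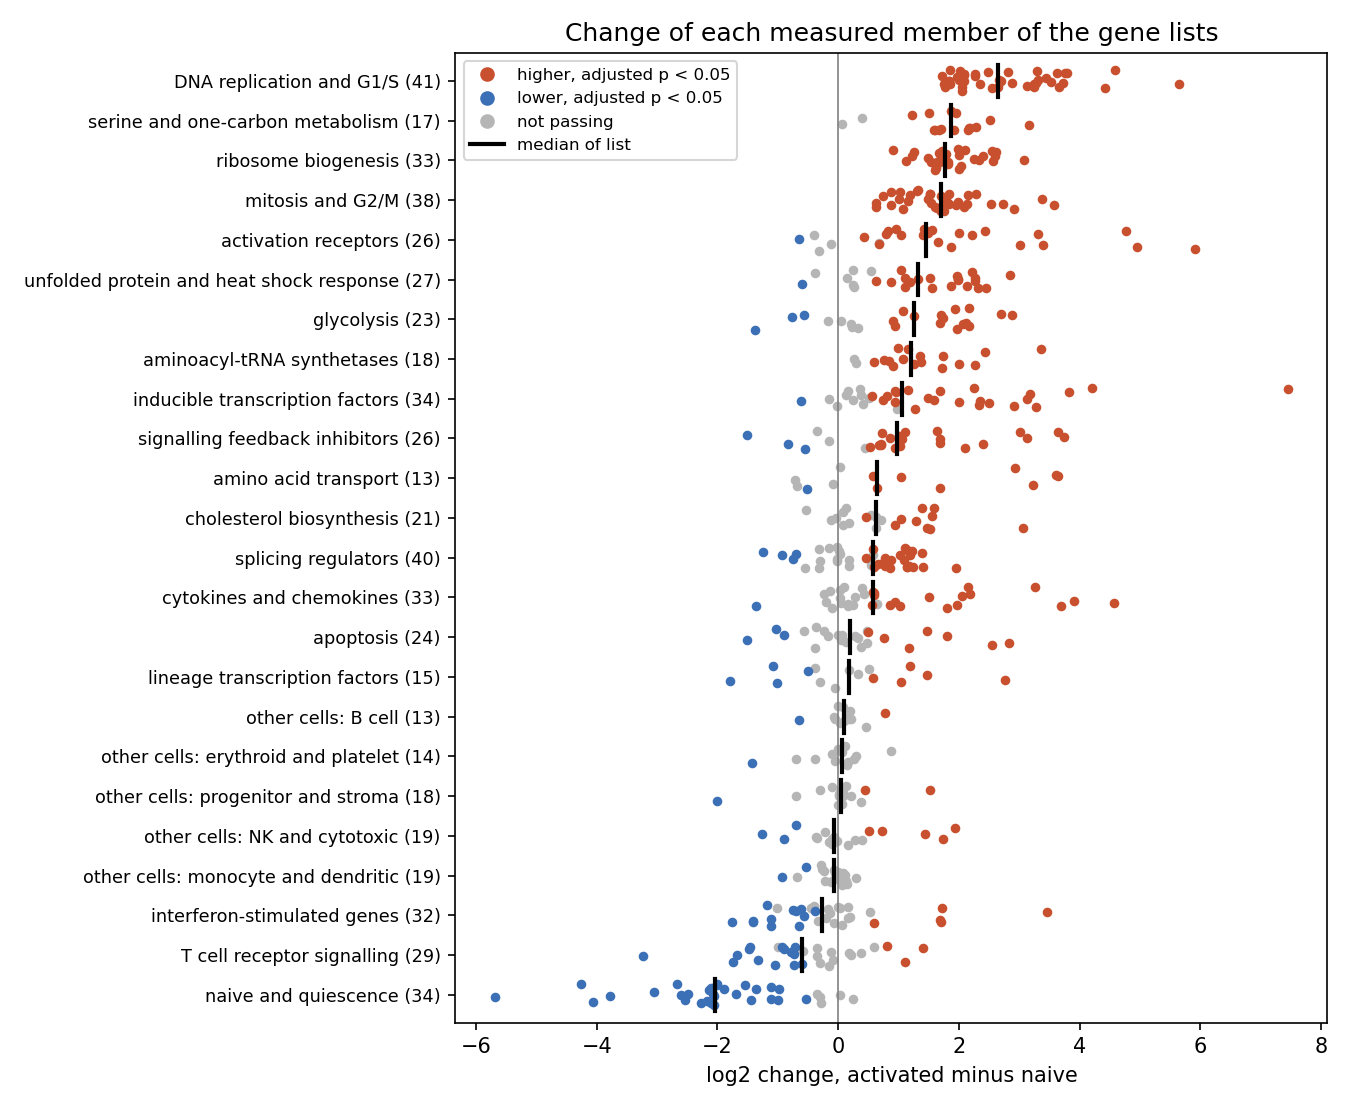
Log2 change (activated minus naive, horizontal axis) of every measured member of 24 gene lists, 1 list per line with the number of measured members in brackets; red and blue points are genes higher or lower at an adjusted p under 0.05, grey points did not pass, and black bars are list medians. The medians run from 2.64 for DNA replication to -2.03 for genes of the naive and quiescent state, and those of the 5 lists of markers of other cells lie between -0.07 and 0.10.

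Markers of cells that a cord blood preparation could also hold were mostly low and changed little, and none of their 5 lists was called. Of 13 B cell markers, CD79B rose by 0.78 ± 0.13 and CD79A fell by 0.64 ± 0.19, or by 0.41 with the raised floor (median of the list 0.10, adjusted p = 0.912). Of 19 monocyte and dendritic cell markers, FCER1G fell by 0.93 ± 0.13 and FCN1 fell by 0.53 ± 0.14 (median -0.07, adjusted p = 0.0789). With the raised floor the change of FCN1 was -0.21 and did not pass (adjusted p = 0.131). The monocyte and dendritic list passed, downward, without naive replicate 1 (adjusted p = 0.0224), without activated replicate 1 (0.0321) and with the median of a gene's probesets (0.0149, the lowest of its alternatives, against a highest of 0.573). The progenitor and stromal list passed, downward, over the genes at or above the median level, where PECAM1 was its 1 member (adjusted p = 0.0406, the lowest of its alternatives, against a highest of 0.957). Among 19 NK and cytotoxic genes 5 rose and 3 fell (median -0.06, mean 0.15, camera down with an adjusted p = 0.688). The largest changes were rises in granzyme B (GZMB, 1.93 ± 0.16), the protease inhibitor CST7 (1.74 ± 0.13) and NKG7 (1.44 ± 0.18, or 0.95 with the raised floor). Of 14 erythroid and platelet genes only HBB, the beta chain of haemoglobin, passed, with a fall of 1.43 ± 0.19 (median of the list 0.06, mean -0.05, camera down with an adjusted p = 0.539). In 18 genes of progenitor and stromal cells PECAM1, which naive T cells also carry, fell by 2.01 ± 0.20, while CD1A rose by 1.51 ± 0.12 and CD1E by 0.44 ± 0.13 (median 0.05, mean -0.0037, camera down with an adjusted p = 0.688). Adjusted over the list alone, 1 B cell marker rose and 0 fell, 1 monocyte and dendritic gene fell, 6 NK and cytotoxic genes rose and 1 progenitor gene rose. The calls of CD1E, FCN1, CD79A and CD79B were lost when single arrays were left out: without naive replicate 1 in all 4 (adjusted p from 0.0787 to 0.177), without naive replicate 2 in all but CD79B (0.122 to 0.232), without activated replicate 1 in CD1E (0.086) and without activated replicate 2 in all but CD79B (0.0895 to 0.181). Over all alternatives the adjusted p ranged from 0.00262 to 0.338 for CD1E, from 0.00669 to 0.139 for FCN1, from 0.00241 to 0.232 for CD79A and from 0.000289 to 0.0787 for CD79B.

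The second comparison asks whether parts of a gene changed differently from the gene as a whole. At the level of single probesets 29009 of 272363 changed, 19857 higher and 9152 lower (limma), a count that rested on all 4 arrays: it was 1036 without naive replicate 1 and 0 without any other single array (limma; at an unadjusted p under 0.05, 50475 without naive replicate 2, 71969 without activated replicate 1 and 69071 without activated replicate 2). It was also 0 with the replicate numbers as a block (limma, 62288 at an unadjusted p under 0.05), 14155 with the raised floor, and 55838 among the probesets at or above the median level. Differential exon usage was called in 1157 of 7590 genes tested (15.2%), and 2202 of 109915 probesets deviated from the rest of their gene, 442 of them in genes without a call. Without naive replicate 1 the test called 347 genes and without naive replicate 2 it called 233. With the replicate block it called 591, with all probesets and genes 3211, and among genes with a log2 change between -1 and 1 it called 350. With only probesets at or above the median in both groups it called 783. The smallest p-values belonged to RRM2, the small subunit of ribonucleotide reductase (adjusted p = 2.45e-21, 13 of 15 probesets deviating), CLSPN, the checkpoint adaptor claspin (7.26e-14, 8 of 29), TCP11L2 (7.97e-14, 9 of 16), RABGAP1L (3.5e-13, 6 of 31), the helicase subunit MCM7 (3.5e-13, 5 of 26) and cyclin D3 (CCND3, 6.52e-13, 3 of 8). These genes themselves changed by 3.30 ± 0.14 (RRM2), 2.13 ± 0.13 (CLSPN), -4.03 ± 0.16 (TCP11L2), -0.71 ± 0.14 (RABGAP1L), 1.84 ± 0.17 (MCM7) and 2.00 ± 0.23 (CCND3). In 1 group RRM2 (naive 5.81), CLSPN (naive 6.20) and TCP11L2 (activated 6.17) lay near the raised floor of 6.09. Their deviations therefore cannot tell relative exon use from probesets that respond with different strength. The error of a deviation is pooled over a gene's probesets, so the p-values also reflect how many probesets a gene has. In CCND3, probeset 2953877 went from 3.02 ± 0.65 to 11.25 ± 0.36 (SD, n = 2), against a median log2 change of 1.30 over the gene's probesets. The naive values lie below the raised floor, with which the change of this probeset was 5.16. Genes changed by over 2-fold were called more often, 694 of 2258, than genes changed by less, 463 of 5332; where probesets of a gene respond to a change with different strength, the test calls them too. Positions of the probesets in the genome were not used here, so no probeset is assigned to an exon. The gene-level call of RABGAP1L was lost without naive replicate 1 (adjusted p = 0.1) and without naive replicate 2 (adjusted p = 0.068), within a range of 0.0002 to 0.1 over all alternatives.

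PTPRC encodes the phosphatase CD45, whose variable exons are known to be skipped after T cell activation. Its exon usage differed between the groups (adjusted p = 0.00436, 41 probesets), and 3 probesets deviated. Probeset 2373878 was less used after activation, at 11.11 ± 0.02 in naive and 9.06 ± 0.21 in activated cells (SD, n = 2), a deviation of -1.45 ± 0.36 (SE) from the rest of the gene (adjusted p = 0.011). Probesets 2373888 and 2373930 were more used, with deviations of 1.33 ± 0.36 and 1.24 ± 0.36 (adjusted p = 0.0267 and 0.0464). The activated arrays disagreed on 2373888: replicate 1 was at 9.66, while replicate 2 (8.41) lay between the naive arrays (8.27 and 8.47). PTPRC as a whole fell by 0.60 ± 0.16 (adjusted p = 0.0357). Both calls were lost when a single naive array was left out and with the replicate block: without naive replicate 1 the adjusted p was 1 for exon usage and 0.27 for the gene, without naive replicate 2 it was 1 and 0.138, and with the block it was 0.16 and 0.0596; the lowest values over the alternatives were 1.28e-06 and 0.00122. Of the 11 measured genes with textbook examples of exon choice in stimulated T cells, 2 rose and 3 fell as whole genes, adjusted over the list alone as well, and camera did not call the list (median -0.19, mean 0.06, camera down with an adjusted p = 0.288). Of them, 10 could be tested for exon usage. Exon usage also differed in HNRNPLL (adjusted p = 5.96e-05, 1 probeset less used), in the glycolytic enzyme PKM (0.00658, 1 probeset less used), which rose by 1.97 ± 0.15, and in the splicing regulator CELF2 (0.0433, with 0 single probesets deviating at an adjusted p under 0.05). CELF2 as a gene had a log2 change of -0.55 ± 0.19 that did not pass (adjusted p = 0.079), though it passed after quantile normalization (0.0063), after median centring (0.00203), over the genes at or above the median level (0.0257) and without activated replicate 2 (0.0124), within a range of 0.00203 to 0.316. The test did not pass for LEF1 (0.0567), FYN (0.0682), CD44 (0.223), MALT1 (0.887), TRAF3 (0.974) and VAV1 (0.98). In 2 of these a single probeset deviated, 2969918 in FYN (-1.15 ± 0.31, adjusted p = 0.0296) and 3326700 in CD44 (-1.05 ± 0.29, adjusted p = 0.0328). Against 4 of the 10, 0 passed when a single naive array was left out (1 at an unadjusted p under 0.05 in each case, limma), 1 passed with the replicate block, 1 among genes with a log2 change between -1 and 1, and 7 after quantile normalization.

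**Figure D3:**
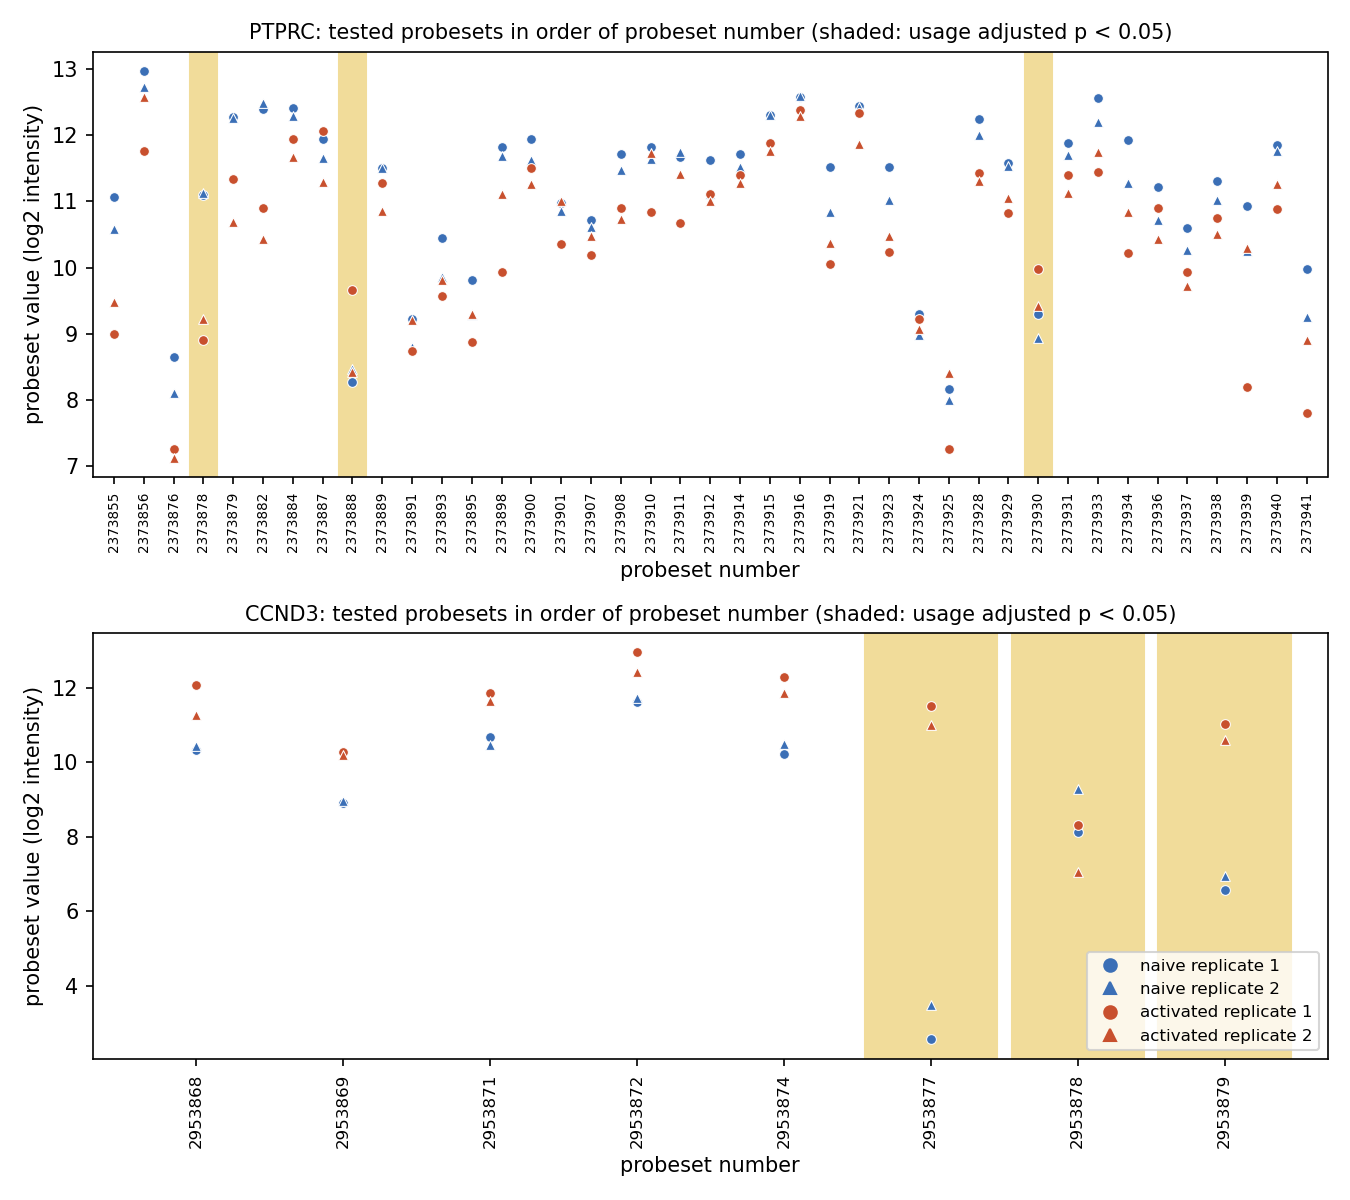
Probeset values (log2 intensity, vertical axis) on each of the 4 arrays for the tested probesets of PTPRC (top, 41 probesets) and CCND3 (bottom, 8 probesets), in order of probeset number, with circles and triangles for single arrays and shading where usage differed at an adjusted p under 0.05. In PTPRC probeset 2373878 the arrays lie at 11.09 and 11.13 in naive against 8.91 and 9.22 in activated cells, and in CCND3 probeset 2953877 at 2.56 and 3.49 against 11.51 and 10.99.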

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

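The raised floor, the log2 of value plus 16, median centring for the named genes and the crossed block were chosen after seeing the data. No called result of the report was called in the opposite direction under any alternative run. Of the tests of named genes under alternatives, 857 kept their direction and side of the threshold, 21 lost and 4 gained the call; for the lists these numbers were 222, 24 and 4. The count of lower genes was 2563 after quantile normalization and 2422 after median centring, against 1473. A minimum fold of 1.5 left 1760 genes (1329 higher, 431 lower), as a stricter hypothesis does. The unmoderated model, which estimates each gene's spread from 4 arrays alone, called 2 genes (1 higher, 1 lower). Changed probesets numbered 29009, 55838 among probesets at or above the median level, which are fewer and brighter, and 14155 with the raised floor; the cause of the last was not tested. Exon usage was called in 3211 genes with all probesets and genes and in 350 among genes with a log2 change between -1 and 1, where fewer were tested. Of the list for exon usage 4 genes passed, 1 in that same subset and 7 after quantile normalization; the cause was not tested. Camera called 17 lists, and 0 with an estimated correlation (2 at an unadjusted p under 0.05).

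Leaving out 1 array at a time gave 2117 to 5697 changed genes, 1504 to 4164 higher and 582 to 1895 lower. Changed probesets ranged from 0 to 1036 (at an unadjusted p under 0.05, 50475 without naive replicate 2, 71969 without activated replicate 1 and 69071 without activated replicate 2), genes with exon usage from 233 to 1571, genes of the exon usage list from 0 to 6 (limma, 1 at an unadjusted p under 0.05 in each case of 0), called lists from 15 to 18 and named genes that kept their call from 74 to 79 of 80. With 1 array fewer there is 1 residual degree of freedom less. Of the 4995 changed genes, 2120 were shared without naive replicate 1, 2060 without naive replicate 2, 4666 without activated replicate 1 and 4557 without activated replicate 2, and 0 had the opposite sign.

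The replicate numbers gave no sign that same-numbered arrays were paired. Their deviations from the group means had a correlation across genes of -0.24, of -0.0966 at or above the median level and of -0.0987 after quantile normalization. The negative sign means that opposite-numbered arrays tended to deviate together. Naive replicate 1 and activated replicate 2 both had the wider spread of gene values in their group. Their 10th percentiles were 5.45 against 5.58 and 5.46 against 5.64, and their 90th 8.98 against 8.85 and 9.51 against 9.29. Quantile normalization, which removes such differences, weakened the correlation. The cause of what remained was not tested. Between groups the gene value correlation was highest for naive replicate 1 with activated replicate 2 (0.872). It was lowest for naive replicate 2 with activated replicate 1 (0.854). With the replicate block 4499 genes changed (3192 higher, 1307 lower), exon usage was called in 591 genes and in 1 of its list, 17 lists were called, 78 named genes kept their call, and 0 probesets changed (62288 at an unadjusted p under 0.05, limma). With the block, PTPRC lost both calls (adjusted p = 0.16 for exon usage and 0.0596 for the gene) and CD1E its call (0.082). A block with crossed numbers gave 6384 genes (4335 higher, 2049 lower). Where a group lies below the raised floor the size of a change depended on the treatment of low values, as in UHRF1 (5.64, or 3.69 with that floor). PMAIP1 and FCN1 lost their calls with the median of their probesets (adjusted p = 0.0506 and 0.0885), FCN1 with the raised floor (0.131) and CD1E with median centring (0.338); the causes were not tested.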

Other observations

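The tests of this part were chosen after the results were seen, except both tests of deviating probesets, whose first forms were written before their results and which were then amended as stated; genes named here beyond the rule were chosen after their values were seen. The interferon-stimulated genes moved both ways. Of 7 measured guanylate-binding proteins, GTPases that act against intracellular pathogens, 5 rose, also after quantile normalization: GBP5 (3.45 ± 0.15 SE), GBP1 (1.73 ± 0.17), GBP4 (1.71 ± 0.20), GBP2 (1.69 ± 0.18) and GBP7 (0.70 ± 0.13). GBP3 (0.29 ± 0.13) and GBP6 (0.31 ± 0.12) did not pass. MX2 (-1.77 ± 0.16), SAMD9L (-1.42 ± 0.15), the exonuclease ISG20 (-1.40 ± 0.14), HERC6 (-1.18 ± 0.14) and the RNA sensor RIGI (-1.12 ± 0.15) fell. Among cytotoxic genes GZMB (1.93 ± 0.16) and GZMH (0.73 ± 0.12) rose, whereas GZMA (-1.27 ± 0.14), GZMK (-0.89 ± 0.11) and the pore-forming PRF1 (-0.71 ± 0.15) fell. The apoptosis genes CASP8 (-1.03 ± 0.16), CASP10 (-0.90 ± 0.17) and BBC3 (-1.51 ± 0.13, or -0.48 with the raised floor) fell.

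IRF8 and the cytotoxic genes GZMB, CST7 and NKG7 are also used by other blood cells, so more B cells, monocytes, dendritic cells or NK cells in the activated samples could raise them. The tables argue against B cells and monocytes as the source for IRF8, which rose by 6.48 even with the raised floor: 13 B cell markers had a median log2 change of 0.0994 (quartiles -0.004 and 0.19, at most 0.78) and 17 monocyte markers one of -0.10 (quartiles -0.28 and 0.06, at most 0.29), though only 1 of each reached the median gene level. For dendritic cells a list was written after 4 markers from the fixed lists had proved too few to decide. Of its 22 measured markers 10 are in other lists, 2 are also used by activated T cells and 5 reached the median gene level. They argue against a rise of dendritic markers as a set, with a median of 0.0265 (quartiles -0.08 and 0.34). CST3 went from 6.47 to 6.46, TYROBP from 5.70 to 5.48 and HLA-DRA from 6.02 to 6.04. Although CD1C (2.21 ± 0.15), LAMP3 (1.73 ± 0.15), CD1A (1.51 ± 0.12), CD74 (0.86 ± 0.17) and CD1E (0.44 ± 0.13) rose, for an untested cause, none came near the change of IRF8. Because the list pools markers of different kinds of dendritic cell, its median and quartiles cannot exclude a gain of 1 kind. For NK cells the values do not decide. The 16 other members of the NK and cytotoxic list did not rise as a set, with a median of -0.11 (quartiles -0.36 and 0.20). Of them 2 rose and 3 fell, against changes of at least 0.95 with the raised floor in GZMB, CST7 and NKG7. Those genes were set apart for having the largest changes of the same list. Only 4 of the 16 others reached the median gene level, so a small rise could be missed. A rise within the stimulated T cells stays open as a hypothesis, as untested, and the method of the CD4+ T cell isolation is not given in the sources used here.

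More genes rose than fell, and the excess depended on scaling. A single scaling factor for every probeset would shift all levels alike, but the groups differed by 0.03 at the 25th and by 0.49 at the 90th percentile of gene values, a difference of 0.46 that exceeds the largest gap between replicates at the 90th percentile (0.22). A stronger signal over the same background on the activated arrays and a true rise of many well-expressed genes cannot be told apart: quantile normalization, which removes both, left 54.5% of the changed genes higher. Activated replicate 2 lay above activated replicate 1 by 0.23 at the 75th percentile and below it by -0.07 at the 25th, a difference whose cause was not tested. The amount of RNA per cell, which the stimulation could raise, was not measured, and no biological explanation was tested.

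Exon usage was called in 30.7% of tested genes changed over 2-fold and in 8.68% of the others, and in the first kind probesets near background that respond little could be a cause: of 1170 deviating probesets in called genes 774 (66.2%) changed less than their gene, and in the group where the gene was higher they lay by a median of -1.51 log2 units from the gene's other probesets (quartiles -2.22 and -0.76). That level met the value set beforehand for this cause, but a low response by itself lowers the level there, so a condition on brightness was added after the value was seen: 36.6% of these probesets were at or above the upper quartile of all probeset values (8.44), and background cannot be told apart from a true loss of those parts of the transcript. In genes changed up to 2-fold background cannot be told apart either. The test set the absolute deviation of 590 probesets from the rest of their called gene against that gene's absolute change. Another 442 lie in genes without a call and were in neither test. For background it was predicted beforehand that a minority would deviate by more than the gene's change, since a flat probeset cannot, and 589 did. Against background, most were to deviate by more than that change plus 1 log2 unit, and 233 did (39.5%, exact binomial interval 35.5 to 43.6). With 2 standard errors in place of 1 log2 unit, a bound tried after the first value was seen, 427 did (72.4%). In the direction of their gene's change 237 deviated, so these changed more than their gene. None of these decides, since the call itself selects large deviations (568 of the 590 were over 1 log2 unit), the gene's change is averaged over dim probesets too, and a probeset can stand above a gene whose other probesets respond little. A change of transcript form and signal from an overlapping or similar gene stay open as untested, for example, chosen after their values were seen, in CHD3 probeset 3709247 (-3.16 with the raised floor, below which its activated values lie, against a median of -0.79 over the gene's probesets as deposited) and PRDM4 probeset 3470071 (-3.16 likewise, against 0.19).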
